A study of Homo sapiens with 14 samples.

How the data were processed

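The series measured binding of the REL domain of human NFATc2, fused to GST, to an Agilent universal 44K array design (HK) by protein binding microarray with Cy5 detection. Per the labels, a slide of 16 grids was divided into 4 chambers of 4 grids; 1 chamber was left single-stranded and the others were copied by primer extension with cytosine, 5-methylcytosine or 5-hydroxymethylcytosine, and the protein was bound to 2 grids per chamber. The files used here cover 14 grids from 7 chambers on 3 slides: 4 of ssDNA, 2 of C, 2 of 5mC and 6 of 5hmC. The general protocol text names other proteins (Zta, CEBPB and cJun|cFos) for the expression step, and the labels differ on which end of the protein carries GST.

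The deposited values are the median foreground signal intensity and the median local background intensity of each spot, on a linear scale, per the file headers. The deposited intensity is neither background-subtracted nor normalised between grids. The scanner and image software are not given in the sources used here, and the scan gain appears only in the names of the files (10 for slide 461, 50 for slide 463, 30 for slide 466). All 40330 spots of each grid are probes. 2 grids (5hmC, slide 463) have another spot layout and were joined by probe identifier. Precision is limited by the number of grids: 2 of each type on a slide. The 2 grids of a type on a slide lie in 1 chamber, so the p-values measure the spread between grids, not between slides or protein preparations. Fits with slide as a block, such as 5hmC against ssDNA, are an exception. Their spread also takes in how the difference between types changed between slides. The number of spots at the top of the scale was 0 to 242 per grid, and at most 2.57% of the spots of a grid did not exceed their background.

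Signals were taken as log2 and centred on the median of the grid, without background subtraction, loess or quantile normalization. For each of 65536 8-mers read along the probe strand, the value on a grid was the median over the probes that hold it in their 35 variable bases; 65127 had at least 1 probe, with a median of 17. 8-mers were kept strand-specific because the modified base lies in 1 strand. Differences were tested with limma (lmFit, and eBayes with a trend), in 1 fit of the 8 grids of slide 466 for ssDNA, 5mC and 5hmC against C and 5hmC against 5mC, and in a fit of the 8 ssDNA and 5hmC grids of slides 463 and 466 with slide as a block. An 8-mer counted as changed at a Benjamini-Hochberg adjusted p under 0.05 over all 8-mers and an absolute log2 difference of at least 0.5. For a motif in an orientation, the shift was the median log2 signal of probes that hold it in that orientation only, minus that of probes that hold it in neither. 43 oriented motifs and, separately, 19 differences between orientations were tested with limma and adjusted within each set. Single values were also compared by exact 2-sided permutation of the grids, within slides where 2 slides hold both types; permuting within slides was chosen after seeing the data. The exact permutation fixed earlier, over all 8 grids without regard to slide, gave p = 0.0286 for both core shifts and the slope per G of 5hmC against ssDNA and p = 0.743 for the orientation difference.

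The comparisons, tests, motif lists and alternatives were fixed before the data were examined, except where stated. The lists were the NFAT core and its next base (GGAAA, TGGAAA, GGAAAA, GGAAAC, GGAAAG, GGAAAT), the core beside CG (CGGAAA, GGAAACG), Rel sites (GGGAAT, GGGGAA), the ETS core (GGAAGT), sites of proteins in the protocol text (AP-1, Zta, C/EBP, CRE), other proteins (Sp1, E-box, GATA, octamer, TATA) and base composition (AAAAA, GGGGG, CG). Members of a list are the 8-mers that contain the motif. The named 8-mers were, per comparison, the 10 that rose most and the 10 that fell most among the changed 8-mers whose grids of 1 type all lay on the same side of the other within each slide, skipping an 8-mer that shared 6 or more bases in a run with one already named. Per DNA type, the 5 8-mers with the highest mean E-score were named by the same skipping, on either strand. E-scores followed the rank-based form used for universal arrays, with strands merged for the double-stranded types and strand-specific for ssDNA, for 8-mers with at least 2 probes. The slope per G came from ordinary least squares of the log2 signal on the counts of G, C and T in the probe.

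The effect of a G at each of 12 positions around the core, the base before the core and the members of lists under other scalings were additions to this plan chosen after seeing the data. Each effect of a G is the median of the probes with it minus that of the probes without it, compared between types.

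The fit was tested on simulated data with 200 changed 8-mers seeded, 100 at a difference of 1 and 100 at 2. For ssDNA against C 84 and 100 were recovered, for 5mC against C 85 and 99, for 5hmC against C 82 and 100, for 5hmC against 5mC 87 and 99, and for 5hmC against ssDNA 96 and 100. The false calls were 5, 2, 3, 3 and 0 in this order. The simulated noise was independent between 8-mers, although real 8-mers share probes, and had the spread between grids of a chamber. It held no chamber effect and no change of the contrast between slides. The recovery and the false calls hold for that setting and not for the measured data.

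Alternatives were normexp background correction with an offset of 50, quantile normalization, Z-scores per grid, detrending over a window of 15 by 15 spots, the mean over probes, leaving out the dimmest 10% of probes, regression on base composition, merged strands or strand-specific E-scores, local background subtracted before E-scores were ranked, slopes without probes that hold GGAAA or TTTCC, the replicate number as a block (also with base composition), all grids with slide as a block, other thresholds, single slides, averaged chambers and leaving out each grid. Requiring at least 8 probes per 8-mer, and single slides for the motif shifts and orientation difference of 5hmC against ssDNA, were added after seeing the data. Leaving out spots marked by the image software could not be run, since the files used here hold no such mark. Where leaving out a grid left 1 grid in a type, that grid was assumed to vary like the other types in the fit. The software was Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, matplotlib 3.10.9, R 4.3.3 and limma 3.58.1.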

Results

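Binding of the Rel-type DNA-binding domain of human NFATc2, a transcription factor of activated T cells that contacts the GGAAA core, was measured on protein binding microarrays with 4 types of DNA. The probes were left single-stranded (ssDNA) or copied into double strands with cytosine (C), 5-methylcytosine (5mC) or 5-hydroxymethylcytosine (5hmC). Each array held 40330 probes, each with 35 variable bases. The modified cytosines lay in the copied strand alone, opposite each G of the probe, so a site was read separately by the strand that held its GGAAA. With GGAAA on the probe strand, the complementary TTTCC of the copied strand carried the modified cytosines. With GGAAA on the copied strand (TTTCC on the probe), the core itself carried none and a modified cytosine was possible only in the flanks or outside the site.

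The 14 arrays (grids) came from 3 slides. Slide 466 held 2 grids of each of the 4 types, slide 463 held 2 of ssDNA and 2 of 5hmC, and slide 461 held 2 of 5hmC. This gave 4 ssDNA, 2 C, 2 5mC and 6 5hmC grids. The median signal on slide 466 was 2517 and 2607.5 for ssDNA, 1744 and 2253 for C, 1932 and 2189.2 for 5mC, and 1432 and 1316 for 5hmC. On slide 463 it was 2152 and 2465.5 for ssDNA and 637 and 624 for 5hmC, and on slide 461 it was 230 and 433.5 for 5hmC. The median ratio of signal to local background lay between 2.30 (5hmC, slide 463) and 13.75 (ssDNA, slide 463). Across probes, the log2 signals of the 2 grids of a chamber correlated with r between 0.646 (ssDNA, slide 466) and 0.957 (5hmC, slide 463), where probes are not independent replicates.

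NFATc2 bound the GGAAA core on the double-stranded types and nearly not at all on single-stranded GGAAA. The shift of a motif is the median log2 signal of probes that hold it in 1 orientation minus that of probes that hold it in neither. On slide 466 the shift of GGAAA on the probe strand was 2.68 ± 0.20 (SD, n = 2) with C, 2.23 ± 0.04 (SD, n = 2) with 5mC, 1.26 ± 0.08 (SD, n = 2) with 5hmC and -0.05 ± 0.02 (SD, n = 2) with ssDNA. For GGAAA on the copied strand it was 1.71 ± 0.21 (SD, n = 2) with C, 2.24 with 5mC, where both grids gave the same value to 2 decimals, 1.58 ± 0.04 (SD, n = 2) with 5hmC and 0.08 ± 0.01 (SD, n = 2) with ssDNA. The 5hmC grids of the other slides had higher shifts: on the probe strand 2.82 ± 0.26 (SD, n = 2) on slide 461 and 3.9965 ± 0.10 (SD, n = 2) on slide 463. For this reason types are compared within slides.

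**Figure D1:**
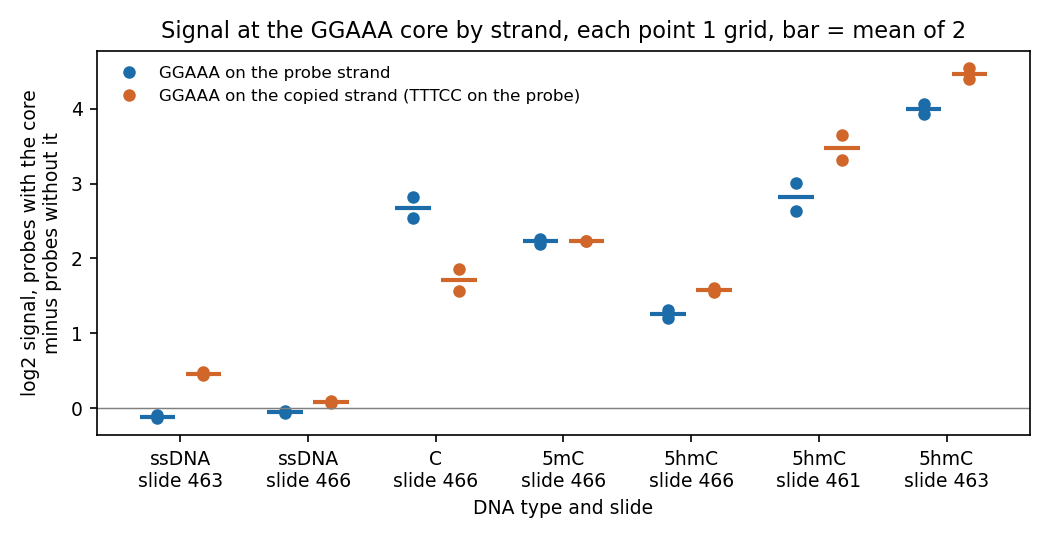
Median log2 signal of probes with GGAAA on the probe strand (blue) or on the copied strand (orange) minus that of probes without the core, for each DNA type and slide; each point is 1 grid and each bar the mean of 2 grids. The ssDNA grids lie near 0 at probe-strand GGAAA, and on slide 466 the probe-strand means are 2.68 for C, 2.23 for 5mC and 1.26 for 5hmC.

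Ranked by enrichment score (E-score, which runs to a maximum of 0.5 and depends only on probe ranks), the preferred 8-mers of the double-stranded types mostly held GGAAA or the shorter GGAA on either strand. With strands merged, GGAAA was held by 64.5% (C), 63.1% (5mC) and 76.1% (5hmC) of the 8-mers above 0.45 on slide 466, and for 5hmC by 72.1% on slide 461 and 70.8% on slide 463; read strand by strand, GGAA on either strand was held by 98.8%, 96.4% and 97.9% on slide 466. With both strands merged, ATTTTCCA had the highest mean E-score in all 3 types: 0.497 (n = 2) for C, 0.493 (n = 2) for 5mC and 0.497 (n = 6) for 5hmC. The next for C were AACGGAAA (0.489), AAGTTTCC (0.487), ATGTTCCA (0.485) and AAATTTCC (0.483). For 5mC they were AGTTTCCG (0.492), GAACGGAA (0.488), TTCCGGAA (0.486) and AAATTTCC (0.479), and the first 3 of these held a CG next to GGAA. For 5hmC they were AAATTTCC (0.487), AACGGAAA (0.487), AAGTTTCC (0.486) and AACTTTCC (0.482). On ssDNA, read on the probe strand over both slides, the highest were ATTTCCAC (0.499), TGTTCCCG (0.485), TTTCCGCG (0.478), AAGTTTCC (0.474) and CGGGGAAA (0.472, from 2 probes). These were also the highest on slide 466 alone, in another order. On slide 463 alone ATTTCCAC was followed by TTTCCGCG, CTGTTTCC, TTCCATGG and GAATTCCG. The number of 8-mers with an E-score above 0.45 was 194.5 ± 2.12 (SD, n = 2) for C, 199 ± 1.41 (SD, n = 2) for 5mC and 197 ± 13.8 (SD, n = 6) for 5hmC, with strands merged; by slide, 5hmC had 180 on slide 466, 204.5 on slide 461 and 205.5 on slide 463. It was 109 ± 35.8 (SD, n = 4) for ssDNA, which is strand-specific, with means of 140 on slide 463 and 78 on slide 466. Read strand by strand, the counts on slide 466 were 406.5 for C, 447 for 5mC and 407 for 5hmC, and 5hmC had 473.5 on slide 461 and 466.5 on slide 463. Of the ssDNA 8-mers above 0.45, a mean of 89.5 on slide 463 and 36 on slide 466 held TTTCC, against 0.5 and 1 that held GGAAA.

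Single-stranded DNA was compared with double-stranded DNA made with cytosine, which sets binding with a second strand against binding without it. Within slide 466, signal over all probes with the core was lower on ssDNA than on C in both orientations. An exception was ATTTCCAC, the 8-mer of highest E-score on ssDNA. Its shift was 2.29 ± 0.13 (SD, n = 2) on ssDNA and 2.04 ± 0.07 (SD, n = 2) on C. The shift of GGAAA on the probe strand fell by 2.72 ± 0.09 (SE, adjusted p = 4.1e-07) and that on the copied strand fell by 1.63 ± 0.09 (SE, adjusted p = 4.2e-06), with both ssDNA grids below both C grids. Of the 253 8-mers with GGAAA on the probe strand, 251 fell and 0 rose, and 251 fell when adjusted over the list alone. Of the 256 with TTTCC on the probe, 249 fell and 0 rose (249 adjusted over the list alone), although 19 rose and 205 fell after quantile normalization. All 48 members of TGGAAA and all 48 of CGGAAA on the probe strand fell, and so did these numbers adjusted over the list alone. Named examples were ATGGAAAA, which fell by 5.06 ± 0.24 (SE) from a mean of 4.91 on C to -0.15 on ssDNA, ATCGGAAA, which fell by 4.66, and GGAAACTT, which fell by 4.47. On the copied strand TTTCCGTC fell by 4.05 and ATTTTCCA fell by 3.93. Of the 10 named 8-mers that fell, 3 held GGGG on 1 probe each; AGCGGGGG and GGGGGCGA, which fell most, by 5.17, lie on the same single probe and are 1 observation.

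By the base after the core, the probe-strand difference of ssDNA minus C was -3.31 at GGAAAA, -2.88 at GGAAAC, -2.36 at GGAAAG and -2.38 at GGAAAT, each past the threshold. The copied-strand differences were -2.39, -1.47, -1.61 and -0.93 in the same order. The Rel sites, bound by the related NF-kappaB proteins, also fell: GGGAAT by 0.52 on the probe strand (adjusted p = 0.0003) and GGGGAA by 0.56 (adjusted p = 0.00056), from shifts of 0.54 and 0.28 on C. Of their members on the probe strand, 18 of 46 and 14 of 31 fell, and 18 and 14 fell adjusted over the list alone, while 1 and 6 rose (2 and 7 adjusted over the list alone). Where an A follows GGGGAA the probe also holds GGAAA, so the GGGGAA values overlap with those of the core. The ETS core GGAAGT fell by 0.37 (adjusted p = 0.00028), with 16 of 48 members lower (16 adjusted over the list alone). Over all 65127 8-mers, 7031 changed, 2522 higher and 4509 lower on ssDNA. The 10 named 8-mers that rose most were dominated by GGGG sequences on 1 or 2 probes each; GGGTGGCC, on 13 probes, rose by 1.28. The balance of rises and falls moved with the scaling, to 5683 and 6020 with Z-scores and to 7414 and 7253 with background correction.

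5-methylcytosine was compared with cytosine to see how methylation of 1 strand went with binding. Within slide 466 the effect depended on the strand and on the base before the core. Sites with CGGAAA on the copied strand, where a 5mC lies directly before the core, rose by 1.77 ± 0.07 (SE, adjusted p = 8.0e-06), from 2.46 ± 0.16 (SD, n = 2) to 4.23 ± 0.04 (SD, n = 2). The same site on the probe strand, with the methyl groups in the complement of the core, fell by 1.12 ± 0.05 (SE, adjusted p = 9.1e-06). TGGAAA, the preferred site on C, fell by 0.70 ± 0.09 on the probe strand (SE, adjusted p = 0.0014) and differed by 0.02 ± 0.13 on the copied strand (SE, adjusted p = 0.89), a value that was -0.09 after quantile normalization. The core as such fell by 0.45 ± 0.09 on the probe strand (SE, adjusted p = 0.009), a call that was lost at -0.42 when 5mC replicate 2 was left out, and rose by 0.52 ± 0.09 on the copied strand (SE, adjusted p = 0.0041).

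All 48 8-mers with TTTCCG on the probe rose (48 adjusted over the list alone), and 47 rose after quantile normalization. With CGGAAA on the probe strand 40 of 48 fell (42 adjusted over the list alone), and with TGGAAA 24 of 48 fell (30 adjusted over the list alone). For the core in all its contexts, 82 of 253 fell and 31 rose on the probe strand (92 and 32 adjusted over the list alone), and 109 of 256 rose and 5 fell on the copied strand (113 and 5 adjusted over the list alone). Named 8-mers that rose were ATTTCCGG, from 0.91 ± 0.25 (SD, n = 2) to 4.06 ± 0.13 (SD, n = 2), a rise of 3.15, CCTTCCGT with 2.55, TTGCTCCG with 2.55, AAGTTCCG with 2.52 and TAATTCCG with 2.47. The last 4 hold TCCG or TTCCG without the full core. TTTTCCTG rose by 2.09, and 2 of the 10 named rises, TTCGGGGT with 2.24 and GGGGTACC with 2.09, lay on 1 probe each. Among those that fell were GTCGGAAA with -1.94, CCGGAACA with -1.70 and GGAAACAC with -1.48, while 6 of the 10 named falls held GGGG on 1 or 2 probes, the largest being CGGGGTCT with -2.73 on 1 probe. GGAAACG, with the CG on the other side of the core, differed by 0.07 on the probe strand (adjusted p = 0.65) and rose by 0.34 on the copied strand (adjusted p = 0.009).

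By the base after the core, the copied-strand sites rose by 0.66 at GGAAAA, 0.64 at GGAAAC, 0.57 at GGAAAG and 0.60 at GGAAAT, and the probe-strand differences were -0.26, -0.31, -0.16 and -0.60. Of the last 4, GGAAAA and GGAAAT passed the threshold; GGAAAC had an adjusted p of 0.05 and GGAAAG one of 0.23. The ETS core GGAAGT fell by 0.34 on the probe strand (adjusted p = 0.0014) and rose by 0.20 on the copied strand (adjusted p = 0.0084). The Rel sites GGGAAT and GGGGAA had probe-strand differences of -0.09 (adjusted p = 0.32) and 0.07 (adjusted p = 0.48). Over all 8-mers, 3284 changed, 2082 higher and 1202 lower with 5mC. This count fell to 1937 after quantile normalization and to 1275 with Z-scores.

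**Figure D2:**
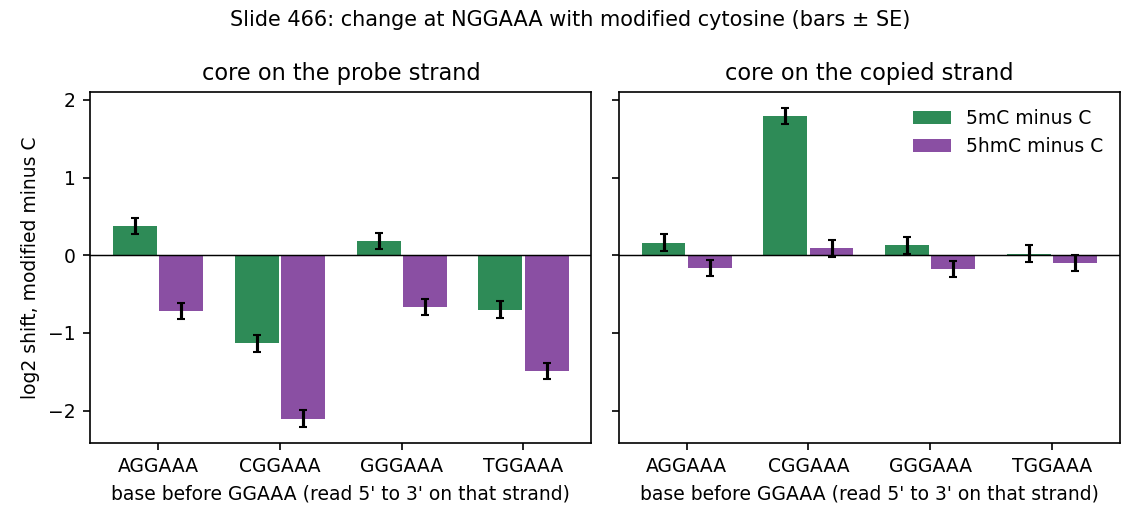
Difference in the log2 shift between each modified cytosine and C on slide 466, by the base directly before GGAAA, with the core on the probe strand (left) or on the copied strand (right); bars are differences of 2 grids against 2 and lines are SE. With 5mC, CGGAAA on the copied strand stands 1.79 above C and CGGAAA on the probe strand lies at -1.14, and 5hmC is below C at all 4 probe-strand sites.

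5-hydroxymethylcytosine, the oxidised form, was compared with cytosine in the same way. Within slide 466, probe-strand sites, whose core complement held 5hmC, fell throughout, and copied-strand sites changed little on balance. GGAAA on the probe strand fell by 1.42 ± 0.09 (SE, adjusted p = 2.8e-05), CGGAAA fell by 2.10 ± 0.05 (SE, adjusted p = 3.5e-07) and TGGAAA fell by 1.49 ± 0.09 (SE, adjusted p = 1.6e-05), with both 5hmC grids below both C grids. On the copied strand the differences were -0.13 ± 0.09 for GGAAA (SE, adjusted p = 0.31), 0.07 ± 0.07 for CGGAAA (SE, adjusted p = 0.46) and -0.08 ± 0.13 for TGGAAA (SE, adjusted p = 0.62); after quantile normalization GGAAA stood at 0.18 and TGGAAA at 0.58. The fall is shown within slide 466 only. Slides 461 and 463 have no C grids, so whether it holds there cannot be told. Their 5hmC grids had probe-strand GGAAA shifts of 2.82 and 3.9965, above the 2.68 of C on slide 466.

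Of the 253 probe-strand members of GGAAA, 219 fell and 0 rose (223 and 0 adjusted over the list alone), against 150 that fell and 1 that rose after quantile normalization. All 48 members of CGGAAA fell (48 adjusted over the list alone), and 44 of the 48 of TGGAAA (47 adjusted over the list alone). On the copied strand, 41 members of GGAAA rose and 42 fell (41 and 42 adjusted over the list alone), and this balance went to 106 and 10 after quantile normalization. Among the named 8-mers, CGGAAAAG fell by 2.86 ± 0.18 (SE), from 4.04 to 1.18, CGGAACTT fell by 2.45, GGAACAAC fell by 2.41 and GTATGGAA fell by 2.37. The 10 that rose most held GGGG on 1 to 3 probes, such as GGGGTATG with 1.86 on 3 probes, and GCCCGGGG and GGGGAGAT lie on the same single probe. Of the 10 that fell most, 6 held GGGG on 1 probe, among them the largest falls, CCCGGGGG with -3.996 and CGGGGAGG with -3.14.

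By the base after the core, probe-strand sites fell by 1.498 at GGAAAA, 1.51 at GGAAAC, 1.22 at GGAAAG and 1.46 at GGAAAT, and GGAAACG fell by 1.21. On the copied strand GGAAAA fell by 0.27 (adjusted p = 0.036), whereas GGAAAC, GGAAAG and GGAAAT differed by 0.11, -0.10 and 0.12 with adjusted p of 0.36, 0.46 and 0.12. The Rel sites fell on the probe strand, GGGAAT by 0.47 (adjusted p = 0.0012) and GGGGAA by 0.44 (adjusted p = 0.0041), and so did the ETS core GGAAGT by 0.45 (adjusted p = 0.00024). The GGGGAA value again overlaps with that of the core. Over all 8-mers, 5549 changed, 2278 higher and 3271 lower with 5hmC. The count fell to 3422 after quantile normalization and to 3071 when all 14 grids were fitted with slide as a block.

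The position of the modified cytosine around a copied-strand core was compared by the effect of a G at each of 12 positions within 6 bases of TTTCC on the probe, on slide 466. A G directly after TTTCC, which puts the modified cytosine directly before GGAAA, added 1.71 ± 0.04 (SE) to the 5mC signal relative to C and 0.30 ± 0.06 (SE) to the 5hmC signal. A G 2 bases after TTTCC added 1.33 ± 0.04 (SE) with 5mC and 1.28 ± 0.04 (SE) with 5hmC, again relative to C. Both values subtract the same C grids, so they are not independent. On the C grids this G had an effect of -0.71, against 0.62 on the 5mC and 0.57 on the 5hmC grids. Relative to C, the effects at the other 10 positions lay between -0.51 and 0.13. No p-value was computed for these effects, which rest on 2 grids of each type.

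**Figure D3:**
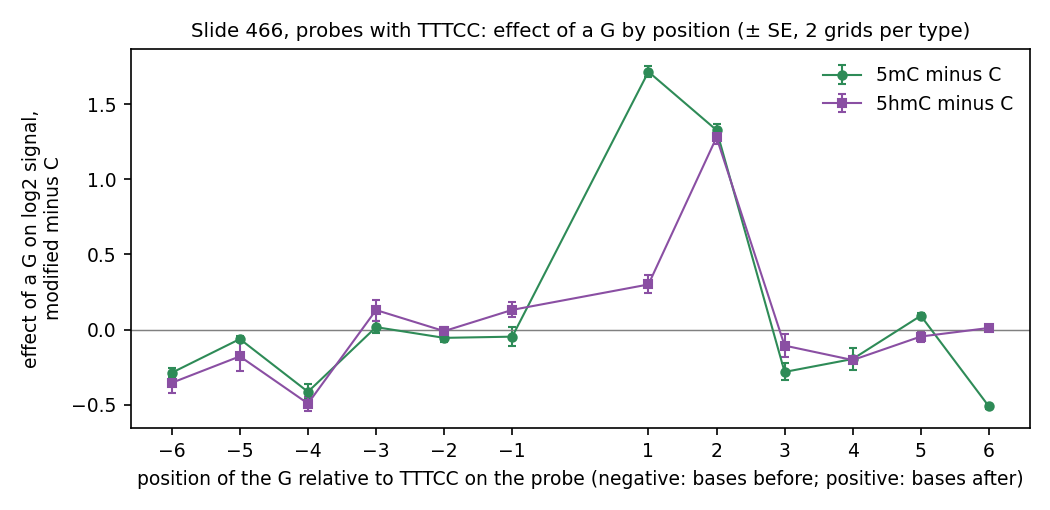
Effect of a G on the log2 signal of probes with TTTCC, as modified cytosine minus C on slide 466, by the position of the G from 6 bases before to 6 bases after the core; points are means over 2 grids per type and lines are SE. The 5mC line peaks directly after TTTCC at 1.71 and stays at 1.33 for 2 bases after, and the 5hmC line peaks at 1.28 for 2 bases after.

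The 2 modified cytosines were compared with each other on slide 466. Each type had 1 chamber there, so the modification cannot be told apart from the chamber. The 99th percentile of the signal was 21978 and 18403 on the 5hmC grids, against 43732 and 45730 on the 5mC grids. Within this slide, signal at the core was lower with 5hmC than with 5mC on both strands. The direction is shown for slide 466 only. Slides 461 and 463 have no 5mC grids, so whether it holds there cannot be told. Their 5hmC grids had copied-strand CGGAAA shifts of 4.23 and 5.38, against 4.23 for 5mC on slide 466. CGGAAA on the copied strand fell by 1.70 ± 0.07 (SE, adjusted p = 1.0e-05), from 4.23 with 5mC to 2.53 with 5hmC, and on the probe strand it fell by 0.98 ± 0.05 (SE, adjusted p = 2.0e-05). GGAAA fell by 0.97 ± 0.09 on the probe strand (SE, adjusted p = 0.00018) and by 0.66 ± 0.09 on the copied strand (SE, adjusted p = 0.00091). TGGAAA on the probe strand fell by 0.79 (adjusted p = 0.0003) but stood at 0.22 after quantile normalization, and on the copied strand it differed by -0.10 (adjusted p = 0.52) and stood at 0.68 after it.

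All 48 8-mers with TTTCCG on the probe fell (48 adjusted over the list alone), against 29 after quantile normalization. Probe-strand GGAAA members fell in 210 of 253 cases (211 adjusted over the list alone), against 97 with 1 rise after quantile normalization. Copied-strand members fell in 118 of 256 cases and rose in 0 (119 and 1 adjusted over the list alone), a direction that became mixed after quantile normalization, with 42 rises and 39 falls. Named 8-mers that fell were TCGTTCCG, from 3.81 to 0.82, AGATTCCG with -2.78, TTCCGGGA with -2.77, TTCCGATT with -2.77 and TTCCGTCT with -2.51; 2 of the 10 named falls and all 10 named rises held GGGG on 1 to 3 probes. By the base after the core, probe-strand differences were -1.24 at GGAAAA, -1.20 at GGAAAC, -1.05 at GGAAAG and -0.85 at GGAAAT, and copied-strand ones -0.93, -0.54, -0.67 and -0.48. GGAAACG fell by 1.28 on the probe strand and by 0.43 on the copied strand. Over all 8-mers, 4854 changed, 1326 higher and 3528 lower with 5hmC than with 5mC, and 2506 changed after quantile normalization.

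5hmC against ssDNA was the only comparison that 2 slides held, with 4 grids against 4 on slides 463 and 466. On slide 463 the 5hmC grids had another spot layout than the ssDNA grids, so type and layout cannot be told apart there. Over all probes with the core, signal rose on both strands and both slides. At ATTTCCAC the shift was 5.85 with 5hmC and 3.98 on ssDNA on slide 463, but 2.16 and 2.29 on slide 466. GGAAA on the probe strand was higher by 2.71 ± 0.58 (SE, adjusted p = 0.0067) and on the copied strand by 2.75 ± 0.51 (SE, adjusted p = 0.0051), TGGAAA by 4.09 and 3.36 (the latter 0.44 and not past the threshold after quantile normalization), and CGGAAA by 2.92 and 3.66. Within slide 463 the GGAAA difference was 4.11 on the probe strand and 4.001 on the copied strand, and within slide 466 it was 1.31 and 1.496. An exact 2-sided permutation of the grids within slides gave p = 0.0556 for both shifts, the smallest value that its 36 arrangements allow.

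Of the 253 probe-strand members of GGAAA, 252 rose and 0 fell (252 and 0 adjusted over the list alone). Of the 256 copied-strand members, 228 rose and 0 fell (235 and 0 adjusted over the list alone), although 190 rose and 15 fell after quantile normalization. Named 8-mers that rose were ATGGAAAA, by 5.68 ± 1.06 (SE) to a mean of 5.53, TTTTTCCG by 5.17, TTTCCAGT by 4.93, TGGAACAT by 4.72 and TTCCGTTC by 4.53. The largest rise, 6.26 at AGCGGGGG and GGGGGCGA, came from 1 probe that holds both, and TGAGGGGT, with 5.51, also lay on 1 probe. Of the 10 named falls, 8 held GGGG on 1 probe and came from 6 different probes, such as ATGCGGGG with -1.49; the others were CGCCGCGC with -1.15 and CGGACGCC with -1.14. By the base after the core, differences were 3.61 at GGAAAA, 2.87 at GGAAAC, 2.44 at GGAAAG and 2.19 at GGAAAT on the probe strand, and 3.48, 2.74, 2.68 and 2.23 on the copied strand. GGAAACG was higher by 2.58 and 2.05. Over all 8-mers, 7651 changed, 5009 higher and 2642 lower with 5hmC. With the 2 grids of a chamber averaged, 4945 changed, 2318 higher and 2627 lower; with base composition regressed out, 3968 changed, 3538 higher and 430 lower.

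The remaining motif lists tested whether sites of other proteins carried signal. The sites of AP-1 (TGACTCA), Zta (TGAGCAA), C/EBP (TTGCGCAA and TTGCGTAA) and CRE-binding proteins (TGACGTCA), which the protocol text names in part, had mean shifts between -0.40 and 0.59 in all types and slides. CRE was higher than on C by 0.51 with 5mC (adjusted p = 0.019) and by 0.63 with 5hmC (adjusted p = 0.0099), AP-1 on the probe strand was higher by 0.18 on ssDNA (adjusted p = 0.003), and Zta passed the threshold in no comparison (lowest adjusted p = 0.099). TTGCGCAA was higher than on C by 0.32 on ssDNA (adjusted p = 0.012) and by 0.29 with 5hmC (adjusted p = 0.033), and TTGCGTAA on the probe strand by 0.41 in both (adjusted p = 0.011 and 0.02). For the sites of unrelated proteins, ssDNA minus C was 0.12 at Sp1 (GGGCGG), 0.14 at the E-box (CACGTG), 0.10 at GATA (AGATAA), 0.26 at the octamer (ATGCAAAT) and 0.01 at TATA (TATAAA) on the probe strand. On the copied strand the octamer differed by -0.53 (adjusted p = 0.00013) and GATA by -0.27 (adjusted p = 0.00063). AAAAA on the copied strand differed by -0.41 between ssDNA and C (adjusted p = 0.00012), and GGGGG on the copied strand by 0.02 (adjusted p = 0.68); probe-strand GGGGG has no shift, since every probe that holds it also holds CCCCC. The dinucleotide CG differed from C by -0.16 with 5hmC (adjusted p = 0.0097) and by 0.07 with 5mC (adjusted p = 0.13). Of the 43 oriented motifs, 35 passed the threshold for ssDNA against C, 23 for 5mC against C, 21 for 5hmC against C, 26 for 5hmC against 5mC and 31 for 5hmC against ssDNA. The 5mC count was 14 when 5mC replicate 2 was left out.

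The preference for one strand of the core was taken as the shift of probe-strand GGAAA minus that of copied-strand GGAAA. The 2 orientations lie on different probes, so the value may also reflect their other bases and places on the probe, which was not tested. ssDNA has no copied strand, so its value compares GGAAA with TTTCC on the single strand and is no strand preference. Its change from C reflects a larger fall at GGAAA (-2.72) than at TTTCC (-1.63). C grids favoured the probe strand by 0.96, 5mC grids had a value of -0.01, and 5hmC grids had -0.32 on slide 466, -0.47 on slide 463 and -0.66 on slide 461. ssDNA had a difference of -0.13 on slide 466, where both shifts lay near 0 (-0.05 and 0.08). On slide 463 its difference was -0.58, with shifts of -0.11 at GGAAA and 0.46 at TTTCC. Relative to C, this difference changed by -1.09 ± 0.05 on ssDNA (SE, adjusted p = 2.2e-10), by -0.98 ± 0.05 with 5mC (SE, adjusted p = 1.1e-09) and by -1.28 ± 0.05 with 5hmC (SE, adjusted p = 3.4e-11). It was -0.31 ± 0.05 for 5hmC against 5mC (SE, adjusted p = 7.9e-05) and -0.04 ± 0.06 for 5hmC against ssDNA (SE, adjusted p = 0.57), where slide 463 gave 0.11 and slide 466 -0.19. At CGGAAA the difference relative to C was -2.88 with 5mC (adjusted p = 1.3e-14) and -2.16 with 5hmC (adjusted p = 3.7e-13). Of 19 such differences, 14, 16, 15, 12 and 13 passed the threshold in the 5 comparisons in the order given above. With 2 grids against 2, an exact permutation test cannot go below p = 0.333; for the GGAAA difference of 5hmC against ssDNA with 4 against 4, the exact p within slides was 0.50.

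The signal also varied with the number of G in the probe, each of which pairs with 1 cytosine of the copied strand. With 5hmC each G in place of an A went with lower signal. The slope was -0.0730 ± 0.00232 log2 per G on slide 466 (SD, n = 2), -0.158 ± 0.0339 on slide 461 (SD, n = 2) and -0.171 ± 0.0101 on slide 463 (SD, n = 2). It was -0.0247 ± 0.00479 with C (SD, n = 2), 0.00138 ± 0.000682 with 5mC (SD, n = 2), and 0.0189 on slide 466 and -0.00527 on slide 463 for ssDNA. Over slides 463 and 466 the slope was lower with 5hmC than with ssDNA by a difference of -0.129, with an exact 2-sided permutation p within slides of 0.0556 (n = 4 against 4), the smallest this design allows. The fall was not particular to G: the slope per C, which pairs with an unmodified G, was -0.0465 on slide 466, -0.0963 on slide 461 and -0.0918 on slide 463 with 5hmC, against -0.0123 with C on slide 466. Without probes that hold GGAAA or TTTCC, the slope per C turned to 0.00691 with C. With 5hmC it was then -0.0375, -0.0880 and -0.0739 in the same order of slides.

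**Figure D4:**
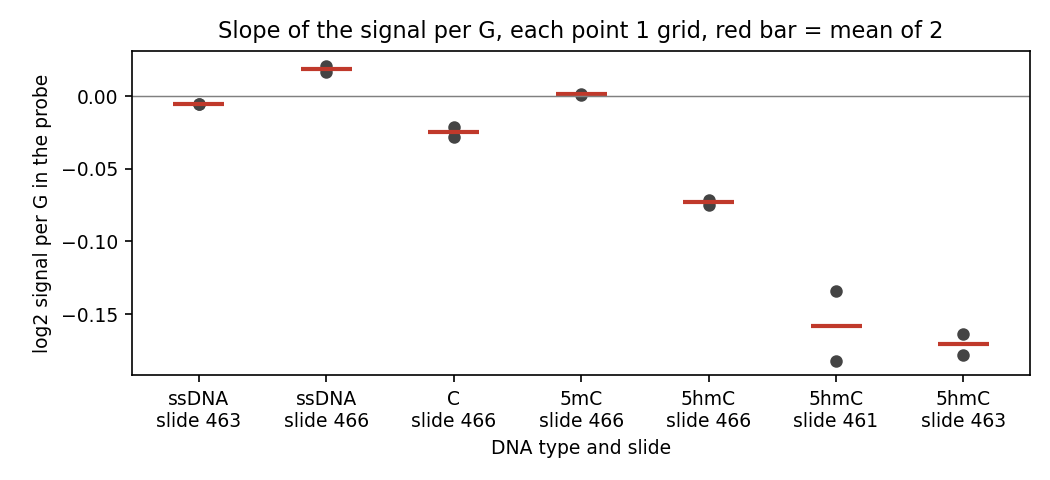
Slope of the log2 signal per G in the probe, from a regression on base counts, by DNA type and slide; each point is 1 grid and each red bar the mean of 2 grids. The 6 5hmC grids all lie below the C grids, with slide means of -0.0730, -0.158 and -0.171 against -0.0247 for C.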

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

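The tests of a single-stranded remainder, of probes made double-stranded, of pairing with the linker, of more complete copying and of the other splits of the grids were chosen after the result was seen.

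The rise of 5hmC over ssDNA at the core differed between the 2 slides that hold both, by an interaction term in limma. The difference of slide 463 minus slide 466 was 2.80 at GGAAA on the probe strand (adjusted p = 6.2e-08) and 2.51 on the copied strand (adjusted p = 6.3e-08), with both grids of each type on slide 463 showing the larger contrast. Local background around the spots is argued against. The 5hmC grids differed between the slides by 2.74 ± 0.09 (SE) as deposited and by 2.803 after background correction. That correction does not remove an even signal inside the spots, so such a signal stays open. DNA left single-stranded in the 5hmC chamber of slide 466 cannot be told apart from other causes: over probes without the core, the mean correlation with the ssDNA grids of slide 466 was higher for the 5hmC grids of slide 466 than for those of slide 463 by 0.009904, less than the spread between pairs of grids. Scan gain, protein preparation and efficiency of copying are tied to the slide and stay open, and no biological explanation was tested, as the DNA type is the same. The spot layout stays open too. The 2 5hmC grids of slide 463 had another layout than all other grids, the ssDNA grids of that slide included.

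The ssDNA grids carried signal in some contexts of TTTCC: its shift over all probes was 0.46 on slide 463 and 0.084 on slide 466, with 2.90 and 1.27 at TTTCCAC, 1.99 and 0.50 at TTTCCAT and 0.066 and -0.27 at TTTCCCT, and the 8-mer of highest E-score, ATTTCCAC, had 3.98 and 2.29. Probes that had become double-stranded are argued against by the mean GGAAA shift of the 4 ssDNA grids, -0.07874 (highest grid -0.033), where C grids had 2.68 at GGAAA and 1.71 at TTTCC. Pairing of AATTTCC with GAAATT of the linker, which would build a short duplex, may contribute but cannot be told apart from a preference for the single strand: probes with AATTTCC exceeded those with TTTCC after another base by 0.4951 to 1.23 on the 4 grids, the lowest just under the 0.5 set for it. The difference was not particular to ssDNA: it was 0.57 and 0.40 on the 5hmC grids of slide 461 and 0.74 and 0.69 on those of slide 463, while on slide 466 it lay between -0.28 and 0.02 on the 5hmC, C and 5mC grids. A preference of the protein for single-stranded TTTCC in these contexts is the other open explanation and was not tested.

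The 5mC rise at TTTCCG was weighed against copying and base composition. Copying with 5mC that was more complete over all probes alike is argued against, since the highest 5mC minus C difference at TTTCCA, TTTCCC or TTTCCT was 0.1632. Copying that varies with the bases beside the core was not tested and stays open. By the 2 bases after TTTCC, sites without a G directly after it ranged from -0.48 at TTTCCAA to 0.90 at TTTCCTG in this difference. Base composition of the probes is argued against, since the difference at TTTCCG stayed at 1.733 with it regressed out. The cytosine directly before GGAAA had an effect of 1.715, but it cannot be the sole position involved, since a cytosine 1 base further away had one of 1.33. The chamber, of which each type had 1 on the slide, and an effect of the methyl groups themselves both stay open and untested.

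Other results that stood out are given as values. The orientation difference of 5hmC minus ssDNA was 0.30 higher on slide 463 than on slide 466 by the interaction term (adjusted p = 0.0021). By the same term, 9478 8-mers had a 5hmC minus ssDNA difference that changed between the slides. The local background, which the comparisons do not use, was higher around probes with the core than around other probes, by 0.60534 on C, 0.60637 on 5mC and 0.72245 on 5hmC grids of all slides (0.475 on slide 466, 0.708 on slide 461 and 0.984 on slide 463), against at most 0.0885 on an ssDNA grid. The shift of the octamer ATGCAAAT on the probe strand was -0.2459 on ssDNA replicate 2 of slide 463, far from the other 3 ssDNA grids; 1 of 98 sets tested had such a grid, and chance gives about 1 in 20 sets.

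For the 7651 8-mers that changed between 5hmC and ssDNA, 1 of the 35 splits of the 8 grids into equal groups, the real one, gave as many, and the highest of the others gave 0. Each other split mixes ssDNA and 5hmC grids in both groups. This puts the difference between types into the spread, which makes few calls likely, so those splits cannot decide about chance. The 8 grids lie in 4 chambers, and 3 splits of whole chambers are too few for a share under 0.05.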

How the results depend on the processing

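The requirement of at least 8 probes and the single slides for the motif shifts and orientation difference of 5hmC against ssDNA were chosen after the result was seen. Signal over local background was lowest on the 5hmC grids of slide 463, and each type had 2 grids of 1 chamber per slide. Of the tests of single motifs under alternatives, 566 kept their direction and side of the threshold, 7 fell short of it, 22 passed it newly and 17 reversed; of those of named 8-mers, 1739 kept both, 100 fell short and 28 reversed. The counts of changed 8-mers stayed within 1.5 times the reported one in 61 of 97 cases. With the replicate block they were 7040 for ssDNA against C, 3314 for 5mC against C, 5568 for 5hmC against C, 4873 for 5hmC against 5mC and 7615 for 5hmC against ssDNA, in which order the following stand. Where a value moved, the cause was not tested, apart from thresholds, merged strands and averaged chambers, which change what is counted or how many grids are compared.

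In that order, no minimum difference gave 18233, 8991, 16020, 13648 and 26124 8-mers, a minimum of 1 gave 1510, 497, 684, 695 and 1635, and merged strands gave 1849, 410, 993, 1063 and 2189. Background correction (normexp) gave 14667 for ssDNA against C, 9564 for 5hmC against C, 8118 for 5hmC against 5mC and 16538 for 5hmC against ssDNA. Quantile normalization gave 1937, 3422 and 2506 for 5mC against C, 5hmC against C and 5hmC against 5mC; Z-scores gave 1275, 3377 and 2529, and 11703 for ssDNA against C. All 14 grids gave 1680, 3071 and 3157 for these 3. For 5hmC against C, spatial detrending gave 3602 and the mean over probes 3644. For 5hmC against ssDNA, the mean gave 14300, base composition regressed out 3968 (3950 with the replicate block), averaged chambers 4945 and slide 463 alone 13307. The share of rises moved by over 10 points with the mean over probes (to 1013 of 10465 for ssDNA against C, 1796 of 2444 for 5mC against C, 812 of 3644 for 5hmC against C, 150 of 3611 for 5hmC against 5mC and 13770 of 14300 for 5hmC against ssDNA), which moved the median of all 8-mers by -0.11 for ssDNA against C and by 0.20 for 5hmC against ssDNA. It also moved without dim probes (1009 of 6773 for ssDNA against C, 6253 of 7483 for 5hmC against ssDNA), with detrending (483 of 3775 for 5hmC against 5mC) with Z-scores (5683 of 11703 for ssDNA against C, 4081 of 7376 for 5hmC against ssDNA) and with background correction (7414 of 14667 and 8068 of 16538 for the same 2). With merged strands the rises were 367, 302, 227, 101 and 1683 in the order above; with a minimum of 1 they were 59 for ssDNA against C, 81 for 5hmC against C, 31 for 5hmC against 5mC and 1597 for 5hmC against ssDNA, and with no minimum 8765 for ssDNA against C, 5564 for 5hmC against 5mC and 12650 for 5hmC against ssDNA. For 5hmC against ssDNA, rises were 3538 with base composition (3518 with the replicate block) and 2318 with averaged chambers.

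The orientation difference of 5hmC against ssDNA reversed to 0.11 on slide 463 alone, 0.30 with the mean, 0.44 with background correction, 0.16 with base composition and 0.27 with quantile normalization, and passed the threshold at -0.19 on slide 466 alone. Leaving out each grid gave 14 to 25 changed motifs for 5mC against C (14 without 5mC replicate 2). 8-mers above the E-score threshold numbered 259 for ssDNA, 466 for C, 480.5 for 5mC and 427 for 5hmC at 0.40, 52.5, 50.5, 47 and 53.2 at 0.48, and 406.5, 447 and 449 strand-specific for the last 3. These means pool slides for ssDNA and 5hmC; on slide 466, which C and 5mC share, ssDNA had 201.5 at 0.40 and 42.5 at 0.48, and 5hmC had 312 at 0.40, 50.5 at 0.48 and 407 strand-specific. Slopes per G were -0.0360 for C and 0.00339 for 5mC with background correction, 0.00221 for 5mC with detrending, 0.0156 for ssDNA (0.0397 on slide 466) and -0.111 for 5hmC on slide 466 with background correction, and -0.0115 for C and 0.0137 for 5mC without core probes.

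After quantile normalization, TGGAAA on the copied strand was -0.094 for 5mC against C, 0.58 for 5hmC against C (0.016 with detrending) and 0.68 for 5hmC against 5mC, TGGAAA on the probe strand 0.22 for 5hmC against 5mC, GGAAA on the copied strand 0.18 for 5hmC against C, and GGAAGT on the probe strand -0.038 for 5hmC against ssDNA (-0.080 on slide 466 alone, -0.028 with background correction). Leaving out each grid gave ranges on both sides of 0 for 5mC against C at copied TGGAAA (-0.20 to 0.24), copied GGGAAT (-0.076 to 0.017) and probe-strand GGGGAA (-0.040 to 0.18), for 5hmC against C at copied GGAAA (-0.28 to 0.012), TGGAAA (-0.30 to 0.13) and CGGAAA (-0.045 to 0.18), and for 5hmC against 5mC at copied GGGAAT (-0.046 to 0.0038). With merged strands, named 8-mers reversed for ssDNA against C: GGGGAGGT -0.057, GCACGGGG -0.057, CCTGGGGA -0.031 and GGGGGCGA 0.031. For 5mC against C these were CCTTCCGT -0.29, AAGTTCCG -0.25, TTCGGGGT -0.15, CGGGGTCT 0.075, CCCGGGGG 0.068, AGGGGCTG 0.066, CGACGGGG 0.12 and CGGGGAGG 0.052. For 5hmC against C they were GGGGTATG -0.20, ATATGGGG -0.23, CAGAGGGG -0.29, GGGGTGTC -0.070, GGGGAGAT -0.21, GGGGCAGA -0.052, GTGGGGCG -0.048, CGGGGTCT 0.013 and AGGGGTGA 0.085. For 5hmC against 5mC they were CAGAGGGG -0.21, GGGGTATG -0.042, CCGGGGGG -0.22 and TACGGGGC -0.32, and for 5hmC against ssDNA AGCGGGGG -0.066, GGGGGCGA -0.25 and TGAGGGGT -0.17.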

Other observations

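The values in this part were chosen after the result was seen, and none was put to a test of its own.

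On copied-strand sites of slide 466, the 2 bases after TTTCC on the probe separated the modified cytosines. With G at both places (TTTCCGG, 73 probes), 5mC exceeded C by 2.64 ± 0.23 (SE) and 5hmC by 1.29 ± 0.24 (SE). With G only directly after the core (218 probes) the differences were 1.45 ± 0.16 (SE) for 5mC and -0.31 ± 0.15 (SE) for 5hmC. With G only 2 bases after it (213 probes) they were 0.99 ± 0.10 (SE) and 0.51 ± 0.10 (SE), and with G at neither (675 probes) -0.12 ± 0.14 (SE) and -0.43 ± 0.16 (SE). The means on 5mC grids for TTTCCGA, TTTCCGC, TTTCCGG and TTTCCGT were 3.97, 4.29, 4.40 and 4.65, against 2.86, 2.39, 1.76 and 3.15 on C grids.

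The shift of TTTCC also varied along the probe. On the C grids of slide 466 the shift of TTTCC was 2.99 when it started at bases 1 to 8, 2.21 at bases 9 to 16, 1.23 at bases 17 to 24 and 0.60 at bases 25 to 31, and on 5mC grids it was 3.25, 3.14, 1.89 and 0.87. In the same order it was 2.50, 2.465, 1.40 and 0.62 on the 5hmC grids of slide 466, 3.84, 4.30, 3.396 and 1.997 on those of slide 461, 5.29, 5.56, 4.22 and 2.28 on those of slide 463, 0.056, 0.061, 0.078 and 0.198 on the ssDNA grids of slide 466, and 0.40, 0.46, 0.49 and 0.55 on the ssDNA grids of slide 463; on slides 461 and 463 the 5hmC shift rose from bases 1 to 8 to bases 9 to 16 before it fell. The base before TTTCC also ranked differently: on the ssDNA grids of slide 466 the shift was 0.27 after A, 0.16 after G, 0.015 after C and -0.046 after T (n = 2 grids), whereas on the C grids of this slide it was 2.36 after T, 1.66 after G, 1.65 after C and 1.24 after A (n = 2 grids). On the ssDNA grids of slide 463 it was 0.95 after A, 0.52 after G, 0.294 after C and 0.303 after T (n = 2 grids).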
